A study of Mus musculus with 35 samples.

How the data were processed

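The series profiled mouse cranial neural crest, the embryonic cells that build much of the face, with and without UTX, a histone H3 lysine 27 demethylase encoded by the X-linked gene Kdm6a. Per the labels, cells were sorted at embryonic day 12.5 from embryos in which Wnt1-Cre switches on a Tomato reporter, keeping Tomato-positive cells that exclude the dead-cell dye DAPI. RNA-seq covers 2 libraries each of wild-type males, male knockouts (Utx floxed on their single X) and female knockouts (both copies floxed). Chromatin immunoprecipitation of H3K27me3 and H3K4me3, on unfixed chromatin digested with micrococcal nuclease, covers 3 wild-type, 3 female knockout and 1 male knockout library per mark. UTX itself was mapped in 1 library of O9-1, a cultured line of cranial neural crest from embryonic day 8.5 embryos, which was fixed first. The labels list 35 samples in all; merged samples hold the peak lists of pooled replicates, and no values were used from the input samples.

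Per the submitters' processing notes, reads were handled with Trimmomatic, TopHat2, Bowtie2, SAMtools, bedtools, HTSeq and MACS2, versions not stated, on genome build mm9. The deposited RNA table holds unnormalised read counts per gene, followed by HTSeq's summary lines. The library kit keeps strand, but the strand setting and the annotation used for counting are not stated, so overlapping genes on opposite strands are uncertain. The deposited histone tables hold raw read counts per MACS2 broad peak, with wild-type and female knockout peaks listed one after another, so a region called in both appears as 2 entries. The deposited peak lists give a score, which equals 10 × −log10 q with decimals dropped, and the −log10 q value itself. The fold enrichment of the UTX list was used as deposited. In both H3K27me3 lists the fold and −log10 p columns hold values that neither can take, and they were not used. The UTX list also carries deposited read counts.

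Of the 23366 genes in the table, 23210 were matched to the GRCm38.p6 gene table, 21525 by symbol and 1685 by synonym, leaving 156 unmatched. That table served for names, chromosome, biotype and gene order only. No mm9 annotation was at hand, so peaks were not assigned to genes and the planned comparison of expression by promoter mark was not made. Coordinates below are 1-based on mm9. Of the list members, Kmt2d, Drg11, Si, Ahsp and Foxf1a had no unambiguous symbol in the table and were not used, while Kmt2c was read as Mll3, Cnmd as Lect1 and Snorc as 3110079O15Rik.

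Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with all 6 RNA libraries in one fit of 3 group means, and p adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were female knockout, male knockout and the mean of both against wild type, and female against male knockout. Peaks were tested the same way on chromosomes 1 to 19, with factors from those peaks. The female comparison used 6 libraries. The lone male knockout library was tested in a fit of all 7, in which it is assumed to vary like the other groups. The same holds for RNA fits that leave out a library and so leave 1 in a group. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, and again with an estimated correlation. The second form rests on the few residual degrees of freedom of 6 libraries in 3 groups, so a list that does not pass it is not shown to be unchanged. fry, run beside camera, tests whether the genes of a list move on balance one way and does not compare the list with other genes. DESeq2 1.42.0 and limma-voom served as alternative tools. Overlaps of peaks (at least 1 bp) were computed with own interval code in Python 3.11.15 with numpy 2.4.6, checked on intervals with known answers, in place of the bedtools run that had been planned. UTX overlaps were set against 1000 shuffles of position within the same chromosome, and fold changes at UTX peaks against 1000 sets of peaks matched on mean count in 20 bins. Shares carry exact Clopper-Pearson 95% intervals (scipy 1.17.1). Intervals, and the floor of 3 counts used for a count of 0, cover counting error only, since the reads carry no molecular identifiers. Plots were drawn with matplotlib 3.10.9.

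The main tests, the 26 gene lists, the rule for named genes and the alternatives called planned in the last paragraph were fixed before the data were examined. The rule names Kdm6a and Uty, the sex chromosome markers in full, and the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the libraries of the groups. It adds up to 4 members per list with the smallest p, the 3 peaks per mark and direction with the smallest p, and the 3 UTX peaks with the highest score. Not every gene so named is described, and some are not reported here. Lists with fewer than 5 tested members would have been described only; all 26 had at least 5.

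On simulated counts made from the real means and library sizes, with 200 genes changed, the gene test for the female comparison recovered 3.5% of genes changed 1.5-fold (14313 tested), 70.5% at 2-fold (14322 tested) and 93.5% at 4-fold (14323 tested). For the male comparison these shares were 3.5% (14334), 72% (14319) and 94.5% (14315). False calls beside these numbered 3, 15 and 18 for the female and 2, 11 and 11 for the male comparison. The list test at the preset correlation recovered 100% of 15 changed genes' list at 2-fold among 14521 genes. Its form with an estimated correlation was not simulated. The peak test for the female comparison, with 200 peaks changed, recovered 33.5% at 1.25-fold (33724 tested), 60.5% at 1.5-fold (33695) and 86.5% at 2-fold (33708) for H3K27me3. For H3K4me3 the shares were 29% (87245), 47.5% (87195) and 79% (87280). False calls numbered 5, 4 and 11 for H3K27me3 and 2, 3 and 2 for H3K4me3.

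The 6 RNA libraries fall into 2 sets by the share of reads assigned to no gene. It was 16.6% to 16.8% in wt1, mko2 and fko1, called set A here, and 20.9% to 21.5% in wt2, mko1 and fko2, set B. The ambiguous share splits the same way, 0.578% to 0.59% against 0.462% to 0.503%. The labels name no such batch. It came to light in this order: same-numbered wild-type and male knockout libraries deviated in opposite directions, crossing the male knockout numbers raised the number of changed genes, and only then was the same split seen in the unassigned reads. A fit with this set as a term is therefore reported beside the planned fit as chosen after its counts were seen. On simulated data with the term, the female comparison recovered 5.5% at 1.25-fold (14378 tested), 52% at 1.5-fold (14376) and 82.5% at 2-fold (14371), and without it 0%, 0% and 38.5%. For the male comparison the shares were 2% (14386), 58% (14373) and 74.5% (14379) with the term, and 0%, 0% and 51% without. False calls with the term numbered 8, 12 and 13 for the female and 4, 21 and 7 for the male comparison. In each run of the planned gene test and of that with the term, except the last (male, 2-fold, with the term), false calls made up a larger share of the calls than the threshold allows, so counts near the threshold are too high by some amount.

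Alternatives planned were other tools, RLE and total-count scaling, a loess offset over mean count (span 0.3), other filters on low counts, a replicate block, leaving out each library, and fitting only the groups compared. A fold threshold for genes and stricter overlaps and peak thresholds were planned too. Chosen after seeing the data were the read-assignment set as a term, all pairings of replicate numbers, a brain marker score as covariate, overlapping peaks collapsed to the longest one, and fold thresholds for peaks. So were separate controls for the agreement between the knockouts. For RNA each knockout was set against its own wild-type library, and for the marks the female knockout was tested against 2 wild-type libraries and the sign of the male knockout taken against the one left, for each of the 3 in turn.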

Results

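The RNA data comprised 6 libraries from sorted cranial neural crest, named here wt1 and wt2 (wild-type males), mko1 and mko2 (male Kdm6a knockouts) and fko1 and fko2 (female knockouts). Reads on genes numbered 15211999, 14513993, 15002409, 16350892, 16301420 and 15409454 in that order. The first principal component of log2 CPM held 54.8% of the variance and placed both wild-type libraries on one side of all 4 knockout libraries. Counts in H3K27me3 peaks were 17030458, 17372670 and 15412991 for wild type, 19088922, 18721731 and 16498829 for the female knockout and 17734520 for the male knockout. Counts in H3K4me3 peaks were 29602898, 22645778 and 35382100 for wild type, 40129294, 35138929 and 34725700 for the female knockout and 38974537 for the male knockout. The UTX library from the O9-1 line held 2995484 counts in its peaks.

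Kdm6a, the targeted gene, was read in every library, at 48.6 ± 4.2 CPM in wild type, 36.2 ± 6.11 in the male knockout and 57.6 ± 6.73 in the female knockout (mean ± SD, n = 2). Its log2 fold change was 0.25 (SE 0.159, edgeR adjusted p = 0.391) in the female and -0.42 (SE 0.161, edgeR adjusted p = 0.198) in the male knockout. A conditional deletion removes part of a gene, so counts over the whole gene do not check the knockout. Xist, the RNA that coats the inactive X, and the Y-linked genes did check the sexes. Xist stood at 1930 ± 483 CPM in the female knockout against 1.34 ± 0.461 in wild type and 1.06 ± 0.519 in the male knockout. Uty, the Y-linked relative of Kdm6a, stood at 36.4 ± 4.28 CPM in wild type, 36.9 ± 3.46 in the male and 0.323 ± 0.457 in the female knockout.

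The comparison of female knockout with wild type asks what the loss of Kdm6a changes where no Uty is present, though knockout females are set against wild-type males, so sex and genotype go together. Regulators of brain and neural tube development fell. Neurog2, a proneural factor, went from 34.4 ± 0.936 to 8.99 ± 1.45 CPM, a log2 fold change of -1.93 (SE 0.172, edgeR adjusted p = 0.00248; n = 2 per group here and below). Of the central nervous system list, 7 of 14 tested members fell and none rose. They included Olig2, needed for motor neurons and oligodendrocytes, at -2.04 (SE 0.233), Barhl1 at -1.67 (SE 0.223) and Otx2 of the fore- and midbrain at -1.35 (SE 0.161), with edgeR adjusted p from 0.00772 to 0.0181. Otx2 went from 27.4 ± 1.2 to 10.7 ± 1.07 CPM.

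Among the largest rises, Myo7a, a myosin of sensory hair cells, went from 2.13 ± 0.389 to 15.8 ± 1.63 CPM (log2 fold change 2.89, SE 0.218, edgeR adjusted p = 0.00101). Ttr, a carrier of thyroid hormone made by the choroid plexus, rose from 40.3 ± 8.86 to 113 ± 13.1 CPM (1.49, SE 0.173). Rgs5, a pericyte gene and the single smooth muscle and pericyte list member of 11 to pass, rose from 4.4 ± 0.394 to 12.8 ± 0.318 (1.54, SE 0.227). Scn10a, a sodium channel of sensory neurons, rose by 1.59, Zfp874a by 1.72, Mettl23 by 1.55 and Hebp2 by 1.45. Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 777 ± 353 to 3420 ± 227 CPM (2.14, edgeR adjusted p = 0.0453). Outside the sex-linked genes, the deepest falls among the genes named were in Gm5506, a gene copy closely related to the enolase Eno1 and so uncertain in its reads, from 55.4 ± 36.1 to 1.5 ± 0.562 CPM (-5.21), and in Nr1h5, a sterol-sensing nuclear receptor, from 16.3 ± 7.06 to 0.518 ± 0.364 (-4.95). Wdfy1, an endosomal adaptor, fell from 69.9 ± 5.35 to 18.6 ± 2.16 (-1.91). The pseudogene Gm10653 (-2.15), Xpnpep2 (-1.94) and Ssc5d (-1.77) also fell.

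Few genes of the crest and face passed. None of 44 craniofacial patterning and palate genes passed the edgeR threshold over all genes, while 3 rose and 2 fell adjusted over the list alone. Among the members with the smallest p were Foxc2 (0.76, SE 0.163, edgeR adjusted p = 0.0639), Osr1 of the palate (0.54, SE 0.129, 0.0915) and Dlx2 of the pharyngeal arches (-0.70, SE 0.187, 0.118). Of 26 neural crest specifiers, 1 fell and none rose. Among UTX and partner chromatin genes, 21 of 22 did not pass and Uty fell. Chd7, the remodeller mutated in CHARGE syndrome, stood at -0.71 (SE 0.189, edgeR adjusted p = 0.118) and Kdm6b, the other H3K27 demethylase, at -0.49 (SE 0.179, edgeR adjusted p = 0.204). With the read-assignment set as a term more members passed: 7 craniofacial genes rose and 6 fell, 5 specifiers rose and 2 fell, and 1 chromatin gene rose and 6 fell.

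As whole lists, camera placed 6 apart from other genes. Central nervous system genes were lower (median log2 fold change -1.25, camera adjusted p = 1.33e-05), as were skeletal muscle genes (-0.70, 0.0405). Hypoxia and glycolysis genes (median 0.40, 16 of 19 positive, 0.00303), proliferation genes (0.24, 26 of 30 positive, 0.00421), Hox genes (0.99, 7 of 7 positive, 0.0405) and chondrocyte genes (0.26, 14 of 17 positive, 0.0446) were higher. The Hox and chondrocyte rises rest mostly on fko2, where the lists' mean log2 CPM, centred over libraries, was 0.792 and 0.567. In fko1 it was -0.209 for Hox genes, beside -0.224 in wt2, and -0.133 for chondrocyte genes, below -0.019 in wt1. None of the 6 lists passed with an estimated correlation: adjusted p = 0.732 with an estimated correlation for the central nervous system, hypoxia and muscle lists, 0.818 for proliferation, 0.775 for Hox and 0.899 for chondrocyte genes. Examples were Ldha, which makes lactate, at 0.71 (edgeR adjusted p = 0.174), Cdk1, which drives mitosis, at 0.48 (0.208), Hapln1, a cartilage matrix linker, at 1.47 (0.0545), and Hoxd1 at 0.99 (0.0579). With the fry test, skeletal muscle genes alone moved on balance one way (adjusted p = 0.0371). That list was read at low levels: its mean log2 CPM was 0.641 in wild type and -0.0248 in the female knockout. Des, for one, had 22 and 22 counts in wild type and 7 and 5 in the female knockout. The estimated correlation of this list was -0.0856, below the preset 0.01, so its lost camera call does not reflect correlated genes. For the other lists set apart here it lay above the preset. It was 0.0716 for central nervous system, 0.105 for hypoxia, 0.402 for proliferation, 0.31 for Hox and 0.741 for chondrocyte genes. For those lists the camera p at the preset correlation may be too small. The estimates are the same in each comparison of this fit. The central nervous system list had 1 rise and 11 falls adjusted over the list alone. No member of the hypoxia, proliferation or skeletal muscle lists rose by that count; 1 skeletal muscle gene fell, and 1 Hox and 1 chondrocyte gene rose. The fit with the set as a term had 11 of 30 proliferation genes higher and none lower, and 9 of 19 hypoxia genes higher and 1 lower.

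The other 20 lists were not set apart by camera. Medians above 0 were BMP targets at 0.37 (adjusted p = 0.123), endothelial genes at 0.31 (0.124), craniofacial genes at 0.19 (0.159), neural crest specifiers at 0.19 (0.227), smooth muscle and pericyte genes at 0.14 (0.185), and osteoblast genes at 0.13 (0.583). Near 0 lay p53 targets at 0.06 (0.701), melanocyte genes at 0.04 (0.917), erythroid genes at 0.03 (0.701), and Schwann and glial genes at 0.02 (0.701). Medians below 0 were macrophage and leukocyte genes at -0.55 (0.124), epithelial genes at -0.20 (0.917), UTX and partner chromatin genes at -0.15 (0.161), FGF targets at -0.07 (0.185), Hedgehog targets at -0.06 (0.701), and extracellular matrix genes at -0.04 (0.917). The median and the camera direction differed in sign for peripheral neuron genes (-0.10, 0.917), Wnt targets (0.03, 0.813) and immediate early and dissociation genes (0.02, 0.917). The sex chromosome markers gave an adjusted p of 0.561, with 2 members higher and 4 lower of 8. Higher were Xist (10.49) and Eif2s3x (0.72, edgeR adjusted p = 0.0491); lower were Ddx3y (-6.82), Eif2s3y (-6.46), Kdm5d (-6.77) and Uty (-6.77). Kdm5c (0.48, edgeR adjusted p = 0.131) and Ddx3x (-0.03, edgeR adjusted p = 0.936) did not pass.

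In the count of genes changed, female knockout vs wild type, edgeR called 163 of 14521 tested, 44 higher and 119 lower, of which 136 changed at least 2-fold and 157 lay outside the sex chromosome markers. DESeq2 called 500, the replicate block 329 and a fit of only the groups compared 33. With the read-assignment set as a term, chosen after its counts were seen, 3384 genes passed (1767 higher, 1617 lower), including all 163. That fit in turn gave 2009, 866, 6043, 6148, 286 and 1697 genes without wt1, wt2, mko1, mko2, fko1 and fko2. Without these libraries the planned fit gave 664, 67, 64, 60, 77 and 1048 genes, so the count varies widely with the libraries in the fit. Where a group is left with 1 library, that library is assumed to vary like the other groups.

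The comparison of male knockout with wild type holds sex constant and leaves Uty in place. Brain genes that fell in females fell here too: Barhl1 fell by 1.68 on the log2 scale (SE 0.223), Otx2 by 1.26 (SE 0.16) and Olig2 by 1.45 (SE 0.223), with edgeR adjusted p from 0.0151 to 0.0204. Of the central nervous system list 7 of 14 members fell, and 1 rose and 11 fell adjusted over the list alone. Further falls were in Foxa1 and Nkx2-2, regulators of the ventral neural tube, from 16.8 ± 4.18 to 4.06 ± 2.25 CPM (-2.06, edgeR adjusted p = 0.0269) and from 9.88 ± 3.41 to 2.6 ± 0.885 CPM (-1.92, 0.0407). Scg5, a neuroendocrine chaperone, fell by 2.05 and the zinc finger gene Sall3 by 1.90.

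In the same libraries a few single regulators of mesenchyme rose, without the craniofacial and osteoblast lists being set apart by camera. Twist2, a brake on bone formation, went from 51.8 ± 7.58 to 111 ± 0.748 CPM (1.10, SE 0.146, edgeR adjusted p = 0.0151). Pax1 went from 48 ± 1.44 to 95.3 ± 12.6 (0.99, SE 0.151, edgeR adjusted p = 0.0199) and Osr1 from 39.5 ± 1.2 to 61.6 ± 2.56 (0.64, SE 0.129, edgeR adjusted p = 0.0414). These were 2 of 44 craniofacial genes, none of which fell; adjusted over the list alone 3 rose and 2 fell. Hoxd1 rose from 3.73 ± 0.0733 to 11.2 ± 1.04 CPM (1.59, SE 0.198, edgeR adjusted p = 0.0151), the single Hox gene of 7 to pass. Hmx1, expressed in craniofacial mesenchyme and cranial ganglia, rose from 2.93 ± 0.833 to 9.33 ± 0.86 (1.67, edgeR adjusted p = 0.0183). Twist2, Pax1 and Hoxd1 did not pass in the female knockout, but the direct test between the knockouts did not set them apart (-0.41, -0.65 and -0.60, each with an edgeR adjusted p of 1). Rgs5 rose by 1.17 and the p53 target Phlda3 by 1.08, while Pou3f1, active in premyelinating Schwann cells, fell by 1.18. Myo7a (2.73), Zfp874a (1.64), Scn10a (1.61) and Lars2 (2.61) rose here too, as did Rn45s, the ribosomal RNA precursor, from 6290 ± 3870 to 41600 ± 13000 CPM (2.73, edgeR adjusted p = 0.0294) and Mir5109 (2.49). Rn45s stood at 32600 ± 3880 CPM in the female knockout, and the 10 most abundant genes took 4.4% and 3.27% of reads in wild type against 6.52% to 8.81% in the knockout libraries. The make-up of the RNA thus differs along with genotype, and a difference in preparation is not separated from loss of Kdm6a for any gene or list here. Nr1h5 (-5.74), Gm5506 (-5.58), Gm10653 (-1.99) and AI854517 (-1.90) fell.

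Camera placed 4 lists apart in the male knockout: central nervous system genes (median -1.30, adjusted p = 1.15e-06), proliferation genes (0.28, 27 of 30 positive, adjusted p = 0.000169), hypoxia and glycolysis genes (0.31, 15 of 19 positive, adjusted p = 0.00697) and Hox genes (0.63, 6 of 7 positive, adjusted p = 0.0481). In the second form of the test none passed, with adjusted p = 0.644 with an estimated correlation for the first and 0.836 for the other 3. The Hox rise rests mostly on mko1: the list's mean log2 CPM, centred over libraries, was 0.683 there. In mko2 it was -0.268, below wt2 at -0.224. None of the proliferation or hypoxia genes passed singly in the planned fit, over all genes or adjusted over the list alone. Adding the set as a term, 12 of 30 proliferation genes rose (22 adjusted over the list alone) and none fell, and 9 of 19 hypoxia genes rose and 1 fell. The other 22 lists had camera adjusted p of 0.131 or more. Of the neural crest specifiers none of 26 passed in edgeR, while 2 rose and 2 fell adjusted over the list alone. Of 22 UTX and partner chromatin genes none passed, with Chd7 at -0.75 (edgeR adjusted p = 0.0763). The fit with the set as a term called 9 craniofacial genes higher and 6 lower, 5 specifiers higher and 3 lower, and 1 chromatin gene higher and 8 lower. Erythroid genes stood apart in 1 library: their mean log2 CPM, centred over libraries, was 1.26 in mko2 and -0.46 in mko1.

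For genes changed, male knockout vs wild type, edgeR gave 340, 55 higher and 285 lower, with 266 at least 2-fold. DESeq2 called 749 and a fit of only the groups compared 938. With the read-assignment set as a term 3589 passed (1744 higher, 1845 lower), including all 340, and 2030, 1122, 3373, 5559, 2960 and 3159 without wt1, wt2, mko1, mko2, fko1 and fko2. In the planned fit the count without each, in the same order, was 897, 158, 3, 2, 981 and 990. The values 3 and 2 come from fits with 1 male knockout library, its spread taken from the other groups.

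**Figure D1:**
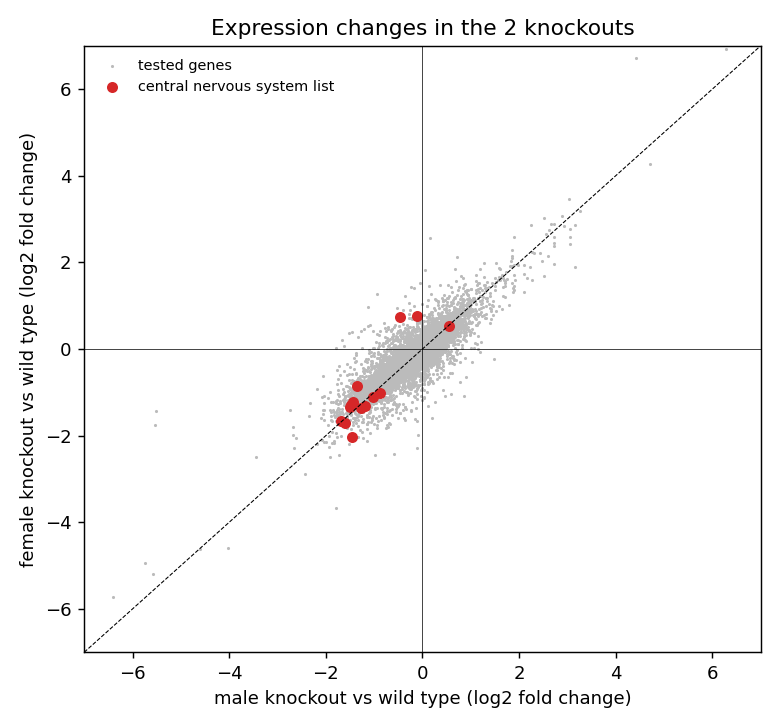
Log2 fold change of each tested gene outside the sex chromosome markers in the male (x) and female (y) knockout against the same wild-type libraries, with central nervous system genes in red and the line of equal change dashed. Most genes lie along the line (r = 0.873 across genes), and most red points lie in the lower left.

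The overlap of changed genes between the 2 knockouts shows how far they moved alike. Outside the sex chromosome markers and any other gene on the Y, 129 genes passed in both, 29 higher and 100 lower, none in opposite directions. Independent lists of these sizes among the 14512 genes left would share 0.159 and 2.26. The fold changes correlated across genes at r = 0.873, and 86.4% of genes had the same sign; genes are not independent replicates. Because both comparisons use the same wild-type libraries, 50 simulations of unchanged groups gave r = 0.506, 66.8% same sign and 0.16 shared genes on average. The covariance was 0.215 against 0.0358 simulated, a difference of 0.179. With a separate wild-type library for each knockout, a split chosen after the results were seen, r was 0.615 (female against wt1, male against wt2) and 0.65 (the reverse). The same sign was then shared by 73.7% and 72.8% of genes, where unrelated changes would give 50%. As wt1 and wt2 lie in different read-assignment sets, a set effect enters the 2 comparisons with opposite signs, so 50% is only a rough mark. A difference common to both wild-type libraries would still count on both sides. The overlap became 408 with DESeq2, 274 with the replicate block, 27 with only the groups compared and 2652 with the read-assignment set as a term, and 547, 48, 3, 2, 65 and 667 without wt1, wt2, mko1, mko2, fko1 and fko2. With the set as a term these became 1535, 634, 2845, 4587, 261 and 1467.

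Setting the mean of both knockouts against wild type gave the widest view of gene groups. Of the central nervous system list 10 of 14 members fell, among them Olig2 (-1.74), Barhl1 (-1.67), Sox1 (-1.41), Wnt8b (-1.39), Lmx1a (-1.32), Otx2 (-1.31), Pax6 (-1.25), Gbx2 (-1.07) and Nes (-0.95). Wnt1 (-1.10, edgeR adjusted p = 0.0555), Pax2 (0.14), Nkx6-1 (0.33) and En1 (0.55, edgeR adjusted p = 0.104) did not pass. Outside the list Neurog2 (-1.86), the brain long noncoding RNA Miat (-1.77) and Rfx4, a regulator of brain patterning (-1.76), fell. Among peripheral neuron genes Nefl, a neurofilament, rose (1.15), and Th, which makes catecholamines (-1.32), and the pan-neuronal Elavl3 (-0.94) fell. Craniofacial genes split: Osr1 (0.59) and Pax1 (0.67) rose, and Dlx2 (-0.72) fell, with edgeR adjusted p from 0.0251 to 0.0379, and 7 rose and 6 fell adjusted over the list alone. Of the crest specifiers Id3, also a BMP target, rose (0.85) and Zic1 (-0.78) fell. Twist2 (0.90) and Spp1, a bone matrix protein (2.00), rose among osteoblast genes, Rgs5 (1.36) and Tagln (0.71) among smooth muscle and pericyte genes, and Hoxd1 (1.29) and Hoxd8 (1.93) among Hox genes. Hapln1 (1.30) and the matrix proteoglycan Dcn (0.51) also rose. Chd7 fell (-0.73, SE 0.159, edgeR adjusted p = 0.0366), as did Spred3 (-0.72) and Des of muscle (-1.39). Des had few counts, 22 and 22 in wild type, 12 and 10 in the male and 7 and 5 in the female knockout.

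Counting genes changed, both knockouts vs wild type, edgeR called 742, 156 higher and 586 lower. With the read-assignment set as a term 4735 passed, including all 742, and 2536, 1397, 5721, 6844, 2711 and 3723 without wt1, wt2, mko1, mko2, fko1 and fko2. Left out in that order, they changed the planned count to 1406, 237, 215, 314, 773 and 2212. By camera, central nervous system genes were lower (median -1.28, adjusted p = 7.82e-06) and hypoxia (0.33, 0.00261), proliferation (0.25, 0.000584) and Hox genes (0.80, 0.0434) higher. None passed in the second form of the test: adjusted p = 0.699 with an estimated correlation for the first pair, 0.858 for proliferation and 0.854 for Hox genes. The centred mean of the Hox list was high in mko1 (0.683) and fko2 (0.792), while mko2 (-0.268) and fko1 (-0.209) lay beside wt2 (-0.224). Medians and camera directions differed in sign for endothelial, epithelial and extracellular matrix genes.

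**Figure D2:**
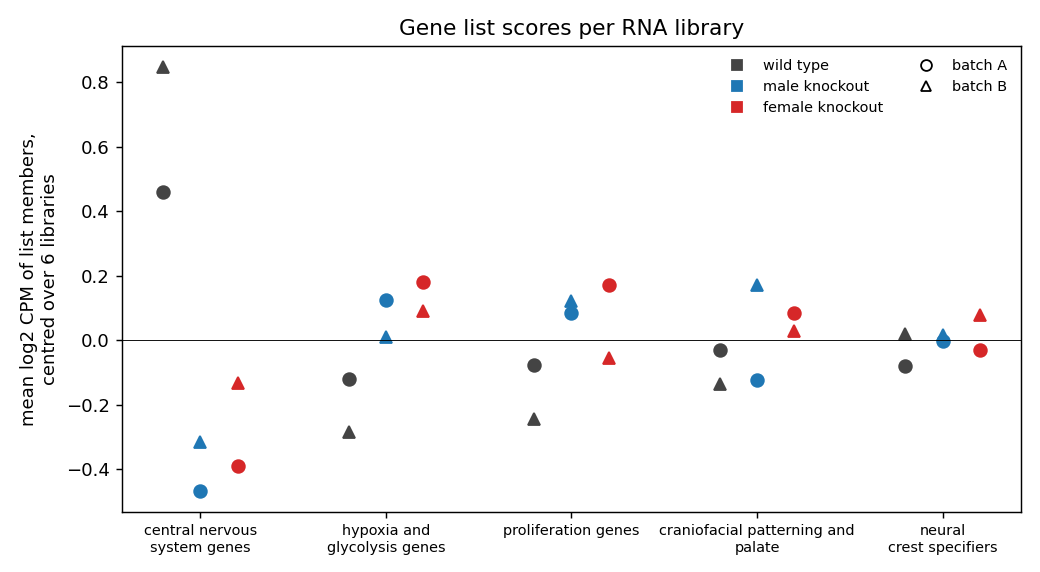
Mean log2 CPM of the members of 5 gene lists in each RNA library, centred over the 6 libraries, with colour for the group and circles and triangles for the 2 read-assignment sets. Both wild-type libraries lie highest for central nervous system genes, at 0.459 and 0.846, and all knockout libraries lie below 0.

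Female and male knockouts differed from each other in sex-linked genes. Xist was higher in females (10.83, SE 0.387, edgeR adjusted p = 8.58e-06) and Uty (-6.79), Eif2s3y (-6.21), Ddx3y (-6.92) and Kdm5d (-6.50) were lower. In the count of genes changed, female knockout vs male knockout, these 5 were all that edgeR called, and 0 of 14513 genes outside the sex chromosome markers passed, against 243 at an unadjusted p under 0.05. Those 243 fall below the share of 0.05 that unchanged genes would give, so they are no sign of further differences. Nor do they show that the knockouts are alike. DESeq2 called 4 genes and limma-voom 1. Without fko1 the count was 9. With the read-assignment set as a term 7 passed, but 21, 20, 352, 530, 13 and 15 without wt1, wt2, mko1, mko2, fko1 and fko2. The further genes, named after their values were seen, were Ttr (1.12, SE 0.121, edgeR adjusted p = 0.0124), at 113 ± 13.1 CPM in female against 51.7 ± 2.64 in male knockouts, and Robo3, an axon guidance receptor (1.29, SE 0.125, edgeR adjusted p = 0.00584). As lists, endothelial genes were higher in females (median 0.21, camera adjusted p = 0.00417), and Wnt targets (-0.15, 0.00417), erythroid genes (-0.80, 0.0151) and skeletal muscle genes (-0.34, 0.0211) lower. None passed: adjusted p = 0.936 with an estimated correlation for erythroid genes and 0.764 for the other 3. The estimated correlation was 0.892 for erythroid genes, 0.284 for Wnt targets and 0.101 for endothelial genes, above the preset 0.01. The skeletal muscle list was read at low levels, with a mean log2 CPM of 0.327 in the male and -0.0248 in the female knockout. No member of the 4 lists passed singly. The erythroid difference rests on mko2: the list's centred mean was 1.26 there, while mko1 (-0.46) lay below both female libraries (-0.01 and -0.23).

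H3K27me3, the repressive mark that UTX removes, changed at many regions by small amounts in the female knockout. The region on chromosome 17 at 35833772–35842391 rose from 7.94 ± 0.632 to 41.8 ± 2.06 CPM (log2 fold change 2.39, SE 0.0698, n = 3), and one on chromosome 11 at 117748577–117753416 from 12.3 ± 0.71 to 41.8 ± 2.49 (1.77, SE 0.0631); its wild-type call at 117749302–117752973 gave 1.84. The lone male knockout library stood at 1.42, 1.12 and 1.17 in these. Regions lower in females lay further along chromosome 17. The one at 36274830–36310359 fell from 337 ± 7.45 to 148 ± 1.98 CPM (-1.19, SE 0.0301), with -1.18 at 36291178–36308555 and -1.10 at 36360390–36377500, where the male knockout stood at -0.29, -0.25 and -0.30. The largest edgeR adjusted p of these 6 was 1.05e-166.

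In the count of H3K27me3 peaks changed, female knockout vs wild type, edgeR called 8729 of 33893 autosomal entries, 4701 higher and 4028 lower, of which 123 and 172 changed at least 2-fold. DESeq2 called 4888 (2793 higher, 2095 lower), and collapsing overlapping entries left 5189. Scaling by total count gave 3540 higher and 5513 lower, so the balance of directions depends on scaling. The tests measure little more than counting error: replicates of one genotype differed by 1.05 to 1.19 chi-square per degree of freedom, and libraries of different genotypes by 1.98 to 4.46. The labels do not say whether the 3 replicates are separate pools of embryos or repeats of one preparation; in the second case n = 3 holds no biological replication, and the p-values of all peaks here cover technical spread alone. Separate wild-type libraries, a test chosen after the results were seen, gave the agreement of the knockouts. Of entries called higher in females against 2 wild-type libraries, 86.3% to 88.6% were also higher in the male knockout than in the one left. Of those called lower, 79% to 82% were lower. In the male knockout 49.1% to 50.9% of all entries went either way. Over all tested entries, called or not, 63.8% to 65.9% went the female way. A difference shared by all wild-type libraries would still count on both sides. The H3K27me3 peaks changed, male knockout vs wild type, numbered 2364 by edgeR, 1457 higher and 907 lower. Total count gave 1095 and 1319 there, and DESeq2 500 and 176 (676 in all), and collapsing left 1412.

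The X chromosome behaved differently. Of 3625 tested H3K27me3 entries on the X, 3446 were higher and 32 lower in the female knockout than in wild-type males, with a median log2 fold change of 1.54. The female knockout list gave 3443 of the X peaks and the wild-type list 289. Each list was chosen by signal in its own genotype, so this choice favours a rise over these entries and a larger X share in females. The X held 4.4% (exact 95% interval 4.39 to 4.41), 4.55% (4.54 to 4.56) and 4.6% (4.59 to 4.61) of counts in peaks in the female knockouts. In wild type it held 2.13%, 2.2% and 2.22%, and in the male knockout 1.32%. H3K4me3 on the X showed a median of 0.09 over 1753 entries, with 457 higher and 146 lower. The 3 H3K4me3 peaks on the X with the largest fitted rises in females, singled out after their values were seen, were at 72980170–72980308 (0, 0 and 0 counts in wild type, 38, 34 and 34 in the female and 0 in the male knockout), at 66073966–66074633 (1, 0 and 1 against 102, 83 and 77, with 185 in the male knockout), and at 100675282–100679819 (21, 13 and 36 against 1737, 1452 and 1423, with 43). Counts in Y peaks were 2472, 1842 and 2813 in wild type, 3452 in the male knockout and 0, 1 and 12 in the female knockouts.

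**Figure D3:**
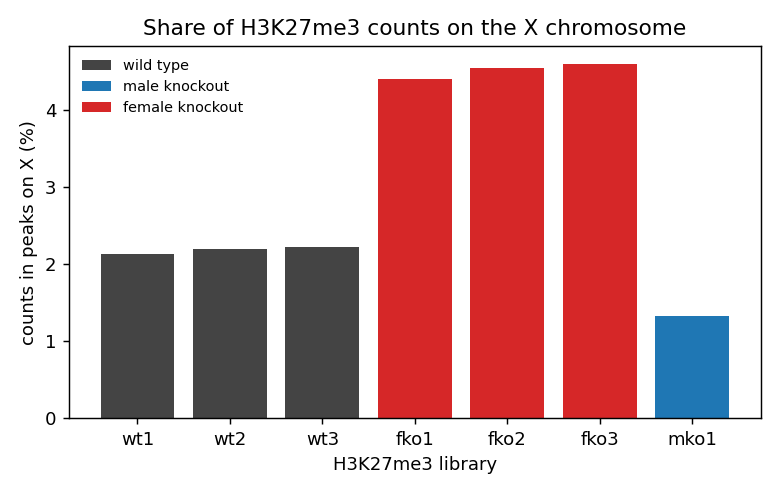
Share of H3K27me3 counts in peaks that lie on the X chromosome, in percent, one bar per library. The 3 female knockout bars stand between 4.4% and 4.6%, above the wild-type bars at 2.13% to 2.22% and the male knockout bar at 1.32%. Of the X peaks counted, 3443 were called in the female knockout and 289 in wild type, which favours a larger share in females.

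H3K4me3, the mark of active and poised promoters, was higher in the female knockout at strong peaks and, over all weak peaks together, lower. The peak on chromosome 2 at 154844109–154846033 rose from 6.52 ± 0.367 to 33.3 ± 1.81 CPM (2.35, SE 0.0634, n = 3; its wild-type call at 154844144–154845588 gave 2.32), and one on chromosome 14 at 50680845–50682932 from 5.31 ± 0.246 to 26.2 ± 1.65 (2.30, SE 0.0692). The male knockout library stood at 2.37, 2.35 and 2.31. The peak on chromosome 1 at 183851666–183852868 fell from 8.29 ± 0.753 to 0.538 ± 0.0761 CPM (-3.94, SE 0.151; male knockout -3.96). One on chromosome 10 at 22002437–22003257 fell from 7.91 ± 0.673 to 0.613 ± 0.107 (-3.67, SE 0.149; male knockout -4.95), and one on chromosome 13 at 23492643–23494725 from 32.7 ± 1.28 to 13.9 ± 0.572 (-1.24, SE 0.0535; male knockout -0.93). The largest edgeR adjusted p of these 6 was 1.19e-55.

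From the lowest to the highest decile of mean count, the median log2 fold change was -0.70, -0.57, -0.54, -0.48, -0.39, -0.23, 0.03, 0.12, 0.15 and 0.18 in the female knockout, and in the male knockout library it ran from -0.88 to 0.23. In the lowest decile the female median was -0.95 for peaks of the wild-type list and 0.06 for those of the female knockout list. Each list was chosen by signal in its own genotype, so this split does not show what lowers weak peaks. For H3K27me3 it ran from -0.05 to 0.04 in females and from -0.22 to 0.04 in the male knockout library. In the count of H3K4me3 peaks changed, female knockout vs wild type, edgeR called 50601 of 88217 autosomal entries, 21897 higher and 28704 lower, with 545 and 7510 at least 2-fold. Peaks of the wild-type list gave 10289 higher and 21496 lower, and those of the female knockout list 11608 and 7208. Total count gave 9935 higher and 35680 lower, DESeq2 22316 and 16037, and a loess offset over mean count 14818 and 13240 (28058 in all); collapsing overlapping entries left 33697, and a mean count of at least 50 left 26874. Total count shifts the median log2 fold change of all H3K4me3 peaks by -0.11 in the female and -0.16 in the male comparison, and the loess offset removes the trend with peak strength by its construction. With separate wild-type libraries, 91.2% to 93.7% of entries called higher in females and 89.5% to 94.2% of those lower went the same way in the male knockout. In that library 45.2% to 47.3% of all entries were higher and 52.7% to 54.8% lower. Over all tested entries, called or not, 78.6% to 83.1% went the female way, so much of this agreement is not particular to the called ones. The limit given for H3K27me3 holds here too. The H3K4me3 peaks changed, male knockout vs wild type, numbered 43967 by edgeR, 20781 higher and 23186 lower. Total count gave 10489 and 31158 there, and DESeq2 18381 and 9287 (27668 in all), and collapsing left 27190. Replicates of one genotype differed by 1.1 to 1.43 chi-square per degree of freedom, and those of different genotypes by 4.19 to 10.8.

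**Figure D4:**
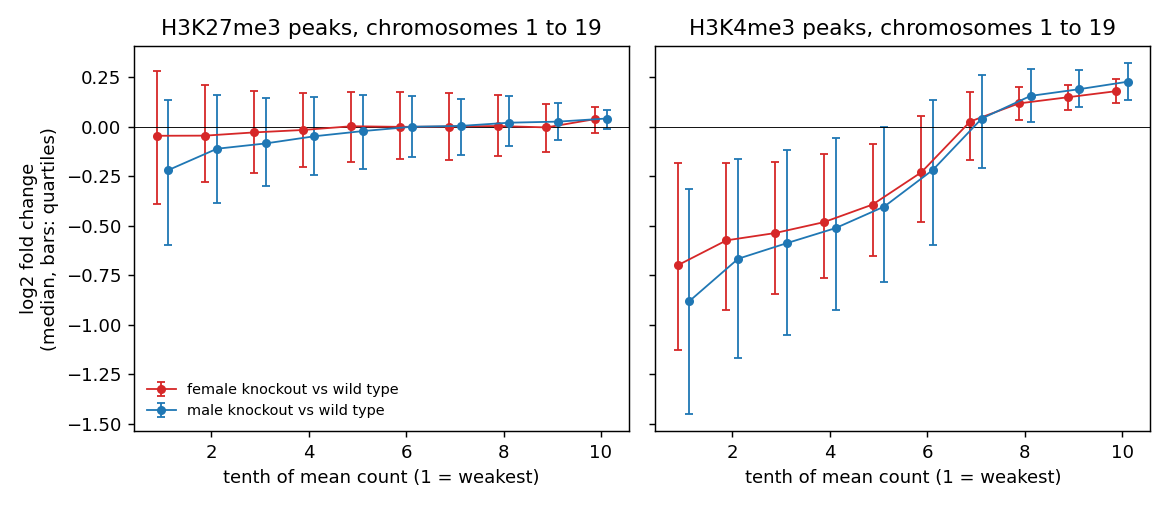
Median log2 fold change (points) with quartiles (bars) of autosomal peaks in 10 deciles of mean count, for each mark in the female and male knockout against wild type. H3K4me3 medians climb from -0.70 to 0.18 in the female and from -0.88 to 0.23 in the male knockout, and H3K27me3 medians from -0.05 to 0.04 and from -0.22 to 0.04.

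The peak lists, called once per genotype on pooled replicates, have no replicate test. Wild type had 17668 H3K27me3 peaks (289 on the X) covering 64.6 Mb and the female knockout 20144 (3443 on the X) covering 78.5 Mb. Of the wild-type peaks 83.4% (14731; exact 95% interval 82.8 to 83.9) overlapped a female knockout peak, and of the female knockout peaks 73.6% (14823; 73.0 to 74.2) a wild-type peak, or 87.3% without X and Y. H3K27me3 peaks that did not overlap had low scores, with medians of 15 and 14 against 40 and 37. The H3K4me3 medians lay closer, at 61 and 74 against 67 and 81. For H3K4me3, 51701 wild-type and 39221 female knockout peaks were listed, and 70.5% (36466; 70.1 to 70.9) and 92.4% (36228; 92.1 to 92.6) overlapped. With peaks of −log10 q of at least 5 these shares were 52.3% and 59.7%, and for H3K27me3 90.5% and 94.9%.

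UTX peaks of the O9-1 line lay on H3K4me3 more often than shuffled positions did, and less often on H3K27me3 than on H3K4me3. Of 23748 peaks, 58.7% (13949; exact 95% interval 58.1 to 59.4) overlapped a wild-type H3K4me3 peak of the sorted crest, against 6.76% for shuffled positions, 8.69 times as many. On H3K27me3 peaks lay 15.6% (3693; 15.1 to 16) against 3.9% shuffled, 3.98 times as many. With at least 50% of the UTX peak covered, 47.7% lay on H3K4me3 and 10.3% on H3K27me3. Both marks held 3430 UTX peaks, H3K4me3 alone 10519, H3K27me3 alone 263 and neither 9536. In reverse, 28.6% of wild-type H3K4me3 and 19.8% of wild-type H3K27me3 peaks held a UTX peak. The highest scores were on chromosome 1 at 122153432–122153899 (434, from 16 counts) and 129518905–129519366 (408, from 17 counts), off both marks, and on chromosome 2 at 157029582–157030871 (388, from 139 counts), on H3K4me3. The mark was mapped in sorted cells and UTX in a cultured line, and UTX had 1 library.

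H3K27me3 entries with a UTX peak had a median log2 fold change of 0.02 in the female knockout, against 0.005 to 0.0134 in 95% of count-matched sets. With the loess offset it was -0.000727 against -0.0107 to -0.00359, again above the matched sets. In this comparison the excess lay in peaks of the wild-type list (-0.00916 against -0.0303 to -0.0176), while those of the female knockout list lay within their range (0.0458 against 0.0345 to 0.0464). In the male knockout library both lists lay above their matched sets, at 0.0185 against -0.00636 to 0.00481 and 0.0389 against 0.0221 to 0.0323. H3K4me3 entries with UTX stood at 0.13 against 0.095 to 0.098 in matched sets, and at 0.000679 against -0.0288 to -0.0249 with the loess offset. Each H3K4me3 matched set needed 27338 entries, and the bins of entries without UTX fell short of this by 14804. Every bin that fell short was drawn with replacement throughout, so the same entries recur within a set. All these ranges cover the draw of peaks and not the spread between libraries, and a region called in both genotypes counts as 2 entries. Sets for H3K27me3 were not matched on H3K4me3, though 3430 UTX peaks lay on both marks and 263 on H3K27me3 alone. A link of these small differences to UTX is therefore not shown.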

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

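The test of female against male knockout was planned for genes, as was counting X peaks apart, whereas the same test for the peaks named below was chosen only after the results were seen.

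Sex-linked genes differ between the knockouts by a direct test. Xist, which coats the inactive X, was higher in female than in male knockouts by a log2 fold change of 10.83. The Y-linked genes Uty (-6.79), Eif2s3y (-6.21), Ddx3y (-6.92) and Kdm5d (-6.50) were lower. These follow from the sexes that the labels give. The female library fko2 still held a few reads on Y genes, 10 on Uty and 19 each on Ddx3y, Eif2s3y and Kdm5d.

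A further 5 genes stood out because both libraries of the female knockout lay on one side of wild type and both of the male knockout on the other. The difference between the knockouts was 0.67 on the log2 scale for Kdm6a, the targeted gene, 1.22 for Tie1, an endothelial receptor, and 0.97 for Perp, a p53 target of epithelia. It was -0.34 for Cdkn1a, a brake on the cell cycle, and -0.12 for Ezh2, the enzyme that places H3K27me3. None of these 5 differences passed the edgeR threshold in the direct test. With 2 libraries per group, some of the many genes named by the rule would lie in this order by chance. That rate was not computed. Tie1 had 10 and 15 counts in wild type, 6 and 7 in the male and 16 and 15 in the female knockout. For Perp the counts were 12 and 12, 6 and 8, and 15 and 13, so both rest on few reads.

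For 6 H3K27me3 peaks the change was in the same direction in both knockouts but of different size, and the difference passed the edgeR threshold. On chromosome 17 at 35833772 the female minus male difference was 0.97 (log2), and on chromosome 11 at 117748577 and 117749302 it was 0.64 and 0.67, all toward more mark in females. On chromosome 17 it was -0.90 at 36274830, -0.93 at 36291178 and -0.80 at 36360390, toward less mark in females. Among H3K4me3 peaks the difference was 1.29 at 22002437 on chromosome 10 (edgeR adjusted p = 0.0462) and -0.30 at 23492643 on chromosome 13 (edgeR adjusted p = 0.00664). The male knockout has 1 library per mark, assumed to vary like replicates close to counting error, sex differs along with the library, and these peaks were picked for the smallest p in the female comparison, which favours a larger change there. The pairs at 117748577 and 117749302 and at 36274830 and 36291178 are overlapping calls of one region. A difference of sex and one of a single preparation stay open and untested. The named H3K27me3 entries on chromosome 17 lie close together, between 35833772 and 36377500. A strain variant carried with a stretch of chromosome, raised below for genes, was not tested for peaks and stays open too.

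The X chromosome was outside the autosomal comparisons of the marks. Its share of H3K27me3 counts in peaks was 4.4%, 4.55% and 4.6% in the female knockouts, above the highest wild-type male share of 2.22%. Of the X peaks counted, 3443 were called in the female knockout and 289 in wild type, which favours a larger share in females. Females carry an inactive X, and no wild-type female was profiled for the marks, so sex and loss of Kdm6a were not separated in females. Among males the 1 knockout library stood at 1.32%, below the wild-type shares of 2.13%, 2.2% and 2.22%, so no rise went with loss of Kdm6a there. Why that library lay lower was not tested.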

How the results depend on the processing

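Chosen after seeing the data were the fits with the read-assignment set as a term, the crossed pairings, the brain marker score as covariate, collapsed peaks and the fold thresholds for peaks; the other alternatives were planned.

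Libraries carry replicate numbers, but numbers did not pair them. Same-number residuals correlated at -0.237 for wild type with male knockout, 0.426 for wild type with female knockout and -0.231 for male with female knockout. For H3K27me3 these correlations were -0.00141, -0.00915 and 0.0146, and for H3K4me3 0.11, 0.0155 and 0.0168. With the replicate block, genes changed, female knockout vs wild type, numbered 329; genes changed, male knockout vs wild type, 481; genes changed, female knockout vs male knockout, 5; and genes changed, both knockouts vs wild type, 818. Crossing the male knockout numbers, which equals the read-assignment set, gave 3384, 3589, 7 and 4735, crossing the female ones 75, 188, 5 and 491, and crossing both 64, 208, 5 and 467. The block gave 8949 H3K27me3 peaks changed, female knockout vs wild type, and 52935 H3K4me3 peaks changed, female knockout vs wild type.

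For genes changed, female knockout vs wild type (163), DESeq2 gave 500, a fold threshold of 0.5 gave 28 and fitting only the groups compared 33. The set as a term gave 3384, that with DESeq2 1892, and the brain score 27. Leaving out 1 library gave 60 to 1048. With the set as a term, leaving out wt1, wt2, mko1, mko2, fko1 and fko2 gave 2009, 866, 6043, 6148, 286 and 1697. limma-voom, RLE factors, no filter and a CPM filter gave 177, 141, 122 and 139.

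For genes changed, male knockout vs wild type (340), DESeq2 gave 749, the fold threshold 12, only the groups compared 938, the set as a term 3589, that with DESeq2 2032, and the brain score 7. Leaving out 1 library gave 2 to 990. With the set as a term, leaving out the same libraries in the same order gave 2030, 1122, 3373, 5559, 2960 and 3159. limma-voom, RLE, no filter and the CPM filter gave 306, 340, 268 and 327.

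For genes changed, female knockout vs male knockout (5), limma-voom gave 1, DESeq2 4, and the set as a term with DESeq2 13. Leaving out 1 library gave 5 to 9, and with the set as a term 21, 20, 352, 530, 13 and 15 in the order above.

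For genes changed, both knockouts vs wild type (742), the fold threshold gave 98, the set as a term 4735, with the fold threshold added 366, with DESeq2 2849, and the brain score 11. Leaving out 1 library gave 215 to 2212, and with the set as a term 2536, 1397, 5721, 6844, 2711 and 3723. DESeq2 alone gave 1113.

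The overlap of changed genes between the 2 knockouts (129) was 408 with DESeq2, 274 with the replicate block, 12 with the fold threshold, 27 with only the groups compared, 2652 with the set as a term, 1457 with that and DESeq2, and 7 with the brain score. Leaving out 1 library gave 2 to 667, and with the set as a term 1535, 634, 2845, 4587, 261 and 1467.

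Results for gene list tests, female knockout vs wild type (6 lists), were 0 with an estimated correlation, 1 with fry and 3 with the set as a term. For gene list tests, male knockout vs wild type (4), gene list tests, female knockout vs male knockout (4), and gene list tests, both knockouts vs wild type (4), the estimated correlation gave 0, 0 and 0, and fry 0, 0 and 1. The central nervous system, hypoxia and proliferation lists passed camera with the set as a term in the comparisons with wild type, while the Hox list did not. None of the 3 passed in that fit with an estimated correlation, with adjusted p of 0.71, 0.71 and 0.917 (female), 0.909 each (male) and 0.766, 0.766 and 0.869 (both). That form of the test has few degrees of freedom here, so the lost calls do not show that the lists are unchanged.

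Among genes named by the rule, leaving out those not reported here, 5786 of 6200 values under the alternatives fixed beforehand kept their direction and side of the threshold, 230 lost the call, 184 gained it and 0 reversed. Under the added fits with the set as a term, 2988 of 4028 kept both, 26 lost the call, 1014 gained it and 0 reversed. With the brain score 10 of 455 reversed, none past the threshold: Nkx2-2 (0.067) and Phlda3 (-0.18) in the male knockout, and with both knockouts Miat (0.30), Id3 (-0.74), Zic1 (0.55), Phlda3 (-0.25), Tagln (-0.11) and Chd7 (0.48). The others were Rfx4, both knockouts vs wild type (0.0286) and Spred3, both knockouts vs wild type (0.0779). The groups explain 91.6% of that score's variance, so the covariate takes up the genotype itself.

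For H3K27me3 peaks changed, female knockout vs wild type (8729), DESeq2 gave 4888, collapsed peaks 5189, and fold thresholds of 0.5 and 1 gave 290 and 33. H3K27me3 peaks changed, male knockout vs wild type (2364), became 676, 1412, 52 and 12. For H3K4me3 peaks changed, female knockout vs wild type (50601), a mean count of at least 50 gave 26874, the loess offset 28058, collapsed peaks 33697, and the fold thresholds 7586 and 365. H3K4me3 peaks changed, male knockout vs wild type (43967), became 27668 with DESeq2, 27190 collapsed, and 10088 and 845 with the fold thresholds. Leaving out 1 library kept these counts at 7150 to 7842, 1825 to 2778, 41005 to 49728 and 37443 to 45396. Named peaks kept direction and threshold in 168 of 168 planned values, and in 31 of 32 added ones; the exception was the H3K27me3 peak on chromosome 17 at 36360390 with the fold threshold of 1.

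Under peak overlap, wild type vs female knockout: H3K27me3, wild-type peaks overlapping a female knockout peak, the share was 90.5% at −log10 q of at least 5 and 76.3% with 50% covered. Under peak overlap, wild type vs female knockout: H3K27me3, female knockout peaks overlapping a wild-type peak, it was 94.9% and 67.8%. Under peak overlap, wild type vs female knockout: H3K4me3, wild-type peaks overlapping a female knockout peak, it was 52.3% and 63.9%, and under peak overlap, wild type vs female knockout: H3K4me3, female knockout peaks overlapping a wild-type peak, 59.7% and 89.6%. Under UTX peak overlap with histone marks: UTX peaks overlapping a wild-type H3K4me3 peak, it was 58.0% and 47.7%, and under UTX peak overlap with histone marks: UTX peaks overlapping a wild-type H3K27me3 peak, 16.6% and 10.3%.

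Fold thresholds, the count filter and collapsing lower counts by their construction; for the other shifts the cause was not tested. With 2 libraries per group the planned gene test recovers few changes below 2-fold, so an unpassed gene is not shown to be unchanged. For the marks, counting error makes up most of the spread between replicates, so depth limits small changes: 33.5% (H3K27me3) and 29% (H3K4me3) of peaks were recovered at the smallest change simulated.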

Other observations

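Chosen only after the results were seen were the tests of the read-assignment set, of shared reads, of peak lists and of enrichment, the removal of histone genes, and the genes named in the next paragraph; the tests of brain cells and of a chromosome stretch were set down first.

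Some genes were nearly off in one genotype and on in the other. In both knockouts against wild type, Nr1h5 and its neighbour Sycp1, a meiosis gene, fell by 5.35 and 5.82 on the log2 scale. Trim12a, an antiviral gene, rose by 4.49 beside the odorant receptor genes Olfr558 (2.89) and Olfr78, the latter with 0 and 0 counts in wild type and 11, 8, 19 and 11 in the knockouts. The histone genes Hist1h2ak (2.92), Hist1h1b (2.74), Hist1h2bb (2.56) and Hist1h2be (2.26) rose. So did the short structural RNAs Rmrp (2.77) and Rpph1 (2.24) and, next to Rpph1, the ribonuclease gene Ang (2.69). The gene copies Gm8615 (-6.06), Gm8994 (-4.61) and Gm5801 (-4.31) fell.

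Only genes outside the sex chromosome markers with a matched chromosome other than X or Y were counted here. Of 39 such genes past the threshold and changed at least 4-fold, 6 neighbouring pairs lay within 10 tested genes of each other. Expression-matched sets gave a median of 1 and at most 3 in 95% of draws, and 4 pairs were left without the histone genes. A strain variant or copy-number difference carried with a stretch of chromosome may therefore account for part of this group. Annotated pseudogenes made up 10.3% of the 39 (4 genes) against 2.56% in matched sets, whose upper bound was 7.69%, so reads shared between gene copies may account for another part. Neither is shown for any single gene. A difference in RNA preparation, not tested, stays open too, since the ribosomal precursor Rn45s, at 6290 ± 3870 CPM in wild type, 41600 ± 13000 in the male and 32600 ± 3880 in the female knockout, and Lars2 and Mir5109 rose along with Rmrp, Rpph1 and the histone genes. Loss of Kdm6a stays open as well.

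Brain genes were lower as a list in both knockouts by camera, a call that was lost in its second form (adjusted p = 0.699 with an estimated correlation). That form has few degrees of freedom here, so the loss does not settle whether the list fell. Pax2 (0.14), Nkx6-1 (0.33) and En1 (0.55) did not go that way, and En1 rose with the read-assignment set as a term (0.56, edgeR adjusted p = 0.0212). The read-assignment set does not account for it, since the list's median was -1.17 and -1.27 within the 2 sets. Fewer brain cells among the sorted cells of the knockouts is a candidate explanation. Sorting for Tomato and against DAPI would remove cells without Wnt1-Cre history, but not brain cells that have this history. Wnt1, itself a list member, was read in every library. Of 572 lower genes outside the list, 74.5% moved the list's way between the sets within the knockout libraries, above the 47.2% to 55.2% of matched genes. The list itself did not move apart there (0.146, within the matched range of -0.147 to 0.201, 8 of 14 members), so the test leaves the explanation open. The tissue expresses 14 of the 16 list genes at a level that could be tested, the most abundant neural one being Nes at 150 ± 42 CPM in wild type, 81.9 ± 2.18 in the male and 74.1 ± 4.59 in the female knockout, so loss of expression within crest cells cannot be told apart from fewer cells. A difference in RNA preparation was not tested and stays open: Rn45s and the share of reads in the 10 most abundant genes also went with genotype.

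Weak H3K4me3 peaks were lower and strong ones higher in the knockouts. In the lowest decile of mean count, peaks of the wild-type list had a median of -0.95 and those of the female knockout list 0.0628. Each list was chosen by signal in its own genotype, so a split of this kind would follow both from calling peaks in one genotype and from a real fall, and the pair is not the mirror image that calling alone would give. Calling therefore cannot be told apart from a fall of weak peaks. Choice by list alone would not raise strong peaks. Those of the wild-type list in the highest decile, whose choice favours a fall, had a median of 0.177, beside 0.183 for the female knockout list. These values depend on scaling factors taken from both lists, which hold 50795 wild-type and 38356 female knockout peaks on chromosomes 1 to 19. Total count shifts the median of all peaks by -0.114, so calling is not excluded as a source of this rise through scaling. The share of counts in the strongest decile of peaks was 44.5%, 44% and 43.9% in wild type, 46.7%, 46.2% and 46.1% in the female and 46.1% in the male knockout, a gap of 1.57 points against at most 0.63 within a genotype. A difference in enrichment between preparations and one between genotypes cannot be told apart here, because the labels do not say which libraries were prepared together.

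For the counts of changed peaks, 1 of 10 splits of the 6 H3K27me3 libraries and 1 of 10 splits of the H3K4me3 libraries, the real one in each case, gave as many: 8729 and 50601, against 0 and 0 as the highest of the others. With 3 libraries against 3, 10 splits are too few for a share under 0.05, and the labels do not say whether the 3 are separate preparations.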
